A study of Nitratidesulfovibrio vulgaris with 2 samples.

How the data were processed

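RNA was sequenced from 2 cultures of Desulfovibrio vulgaris Hildenborough, 1 library for each condition, so samples were grouped by the condition in the labels and every group held 1 library. The poised-electrode sample is titled only "2" in the labels, and its source name gives the poised electrode. Columns of the count table were assigned by the sample title that begins their names, and every direction given here rests on that match. Per the labels, cells from the poised condition were pipetted off the indium tin oxide electrode in a buffer with lysozyme before RNA extraction, ribosomal RNA was removed with a bead kit for Gram-negative bacteria, and libraries were made with a stranded kit. The labels give the control both as an open-circuit incubation in a glass vial without an electrode and as an incubation in an H-type reactor, so the vessel of the control is uncertain. The presence of an electrode, its potential, attachment to its surface and the way the cells were collected differed together between the libraries.

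The submitters' processing notes name Trimmomatic 0.38, Bowtie 1.1.2, HTSeq 0.10.0 and edgeR, without giving their roles or settings. Read counts per annotated feature were deposited by the authors, per the file headers, for 3318 features of the chromosome and the megaplasmid. FPKM values were deposited beside them, and recomputing them from the count, the gene span and the column total of the authors' table gave the deposited FPKM values to the last decimal printed. The authors also deposited a comparison table with a signed fold change as a score (negative where the poised electrode was lower), a mean log2 CPM and raw and adjusted p-values, per the file headers. In that deposited table every absolute fold is at least 2 and every raw p-value is below 0.05, and the dispersion behind those p-values is not given in the sources used here. Whether strand was used in counting is not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart. How reads that align to several places were treated is likewise not given. The 10 features for 16S and 23S ribosomal RNA, which are present in several copies, together held 17 counts in both libraries, so these counts were not used to gauge how well ribosomal RNA was removed. Gene ontology tables from the same series were not used here because they give no background.

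Features are named by their older locus tag where the count table gives one, otherwise by the newer tag, with gene symbols from the count table and from a RefSeq gene table of the organism, which matched 3272 of the 3318 features by locus tag. Symbols were available for 707 features. Coordinates are those of the authors' count table, counted from 1 on the main chromosome, and span whole coding sequences. No genome sequence was used, so GC content was not checked.

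The gene counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, giving factors of 0.915 for the poised-electrode and 1.09 for the open-circuit library. A prior count of 2, scaled to library size, was added before the log2 ratio of poised electrode over open circuit was taken. Features with a mean count of at least 10 over both libraries were kept (3006 features, 2988 of them protein-coding), and a feature was called higher or lower at a ratio of at least 2-fold. Since 1 library per group leaves no residual degrees of freedom, no test between conditions was made. Each ratio has an exact conditional binomial (Clopper-Pearson) 95% interval without a prior count. Such intervals cover counting error only. They may be too narrow even for that, since reads without molecular identifiers are not independent molecules. A count of 0 is compatible with up to 3 counts, or 0.237 CPM in the poised-electrode and 0.414 in the open-circuit library. Tested features had a median count of 787.5 and 465.5 in these libraries.

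A total of 32 gene lists were fixed before the data were examined, by locus tag, symbol or product name. A list with at least 4 measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of its size, drawn within 10 bins of mean expression. It was said to stand apart at a percentile of 2.5 or lower or 97.5 or higher, as a description of these libraries. With 30 lists evaluated, 9 stood apart, 4 higher and 5 lower, where chance alone places 5% of independent lists beyond these limits. Percentiles do not depend on a shift of all ratios. The 2 lists without a percentile were iron storage and the megaplasmid genes.

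Named genes followed a rule fixed in advance: the 10 highest and 10 lowest ratios among the 2632 protein-coding genes with a mean count of at least 100, and from each list standing apart the members with the highest ratio, the lowest ratio and the highest mean expression. For sulfate reduction, periplasmic hydrogenases and formate dehydrogenases the same examples were taken whatever their values, with 4 cytochrome genes, and other lists gave their highest and lowest ratios. Where 5 or fewer members of a list were past 2-fold on 1 side, these were named too, which adds rpsP, uvrC, mutL, rho, DVU3143 and DVU3145 after their values were seen.

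The procedure was tested on simulated Poisson counts for the comparison of poised electrode with open circuit, with 200 genes altered and 3001 features passing the filter. Equal numbers were raised and lowered, all by more than the 2-fold limit, unlike the data, where far more features were higher than lower. The simulation therefore does not test the centring of TMM under such a split, nor changes near the limit. All genes altered by 1.5 on the log2 scale and all altered by 2 were called in the right direction (100% each), and 3 of 2802 unaltered features were called. Intervals held the true ratio for 95.6% of features. Of 400 lists of 20 features drawn at random from the simulated table, 5.0% lay beyond the percentile limits. That share follows from drawing features singly, and says nothing of lists whose genes vary together. Alternatives were total-count, upper-quartile and DESeq2 1.42.0 size-factor scaling, a prior count of 0.5, no filter or a mean count of at least 100, a 4-fold limit, intervals wholly past 2-fold, leaving out the 20 features with the most counts, thinning the deeper library to an equal total count (effective library sizes were then recomputed and still differed), list means and matching lists on gene length. After the data were seen, TMM over protein-coding genes, removal of the trend on gene length (lowess, fraction 0.5, statsmodels 0.14.6) and centring on the mode of the log2 ratios were added. Lists and intervals were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.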

Results

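The data were transcript counts from Desulfovibrio vulgaris Hildenborough, a sulfate-reducing bacterium now placed in the genus Nitratidesulfovibrio. Cells incubated for 7 days on an indium tin oxide electrode poised at -0.2 V against the standard hydrogen electrode, with the electrode as electron donor and sulfate as electron acceptor, gave 1 library. Cells incubated for 7 days under open circuit, per the labels without an electrode and so without that donor, gave the other. The comparison addressed which genes differ in transcript abundance when the cells are supplied with electrons by a cathode. The poised-electrode library held 12645019 counts and the open-circuit library 7243156 counts over the 3318 annotated features, of which 9293697 and 5529833 counts fell on protein-coding genes. A pair of stable RNAs led both libraries. The RNA of ribonuclease P (rnpB) took 15.3% of the poised and 13.2% of the open-circuit counts, and transfer-messenger RNA (ssrA) took 11.2% and 10.4%. With 1 library per condition no difference has a replicate check and no p-value was computed. Ratios are given with 95% intervals that cover counting error only, and they compare these libraries, not the conditions. The presence of an electrode, attachment to it and the way the cells were collected differed along with the potential.

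Far more genes were higher than lower on the poised electrode. Of 3006 features with a mean count of at least 10, 543 were at least 2-fold higher on the poised electrode, 26 were at least 2-fold lower, and 2437 lay within 2-fold. Scaling by total counts gave 427 higher and 86 lower features (83.2% higher) and upper-quartile scaling 430 and 81 (84.1%), compared with 95.4% higher in the 543 to 26 split. Intervals wholly past 2-fold left 424 higher and 12 lower. Protein-coding genes made up 537 of the higher and 26 of the lower features. Among protein-coding genes with a mean count of at least 100, the highest ratios belonged to the hypothetical protein DVU3044 (29.9-fold, interval 18.0 to 83.5), the sodium/proton antiporter gene nhaC (DVU0381, 28.0-fold) and the hypothetical proteins DVU_RS10535 (21.8-fold) and DVU2130 (20.7-fold). The next were the hypothetical protein DVU2760 (19.6-fold), the helix-turn-helix regulator DVU1645 (19.5-fold) and the copper/zinc efflux transporter DVU3386 (18.2-fold, 17.2 to 19.3). The response regulator DVU1970 (17.5-fold, 10.6 to 45.2) and the hypothetical proteins DVU3333 (15.4-fold) and DVU0974 (13.6-fold) completed the 10. DVU3386, on the main chromosome from 3559448 to 3560803, stood out by depth, with 31375 counts on the poised electrode and 1180 under open circuit (1829.8 and 120 FPKM). DVU3044 had 419 and 8 counts, and nhaC, from 431111 to 432502, had 1087 and 25.

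**Figure D1:**
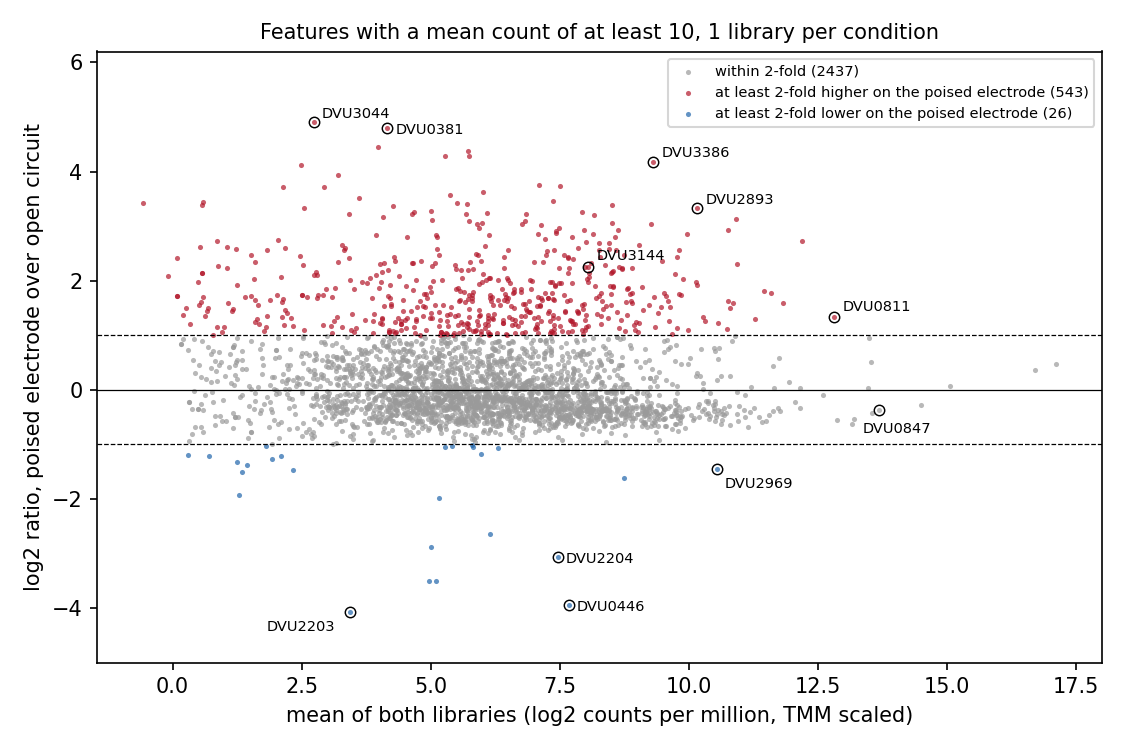
Log2 ratio of TMM-scaled counts, poised electrode over open circuit, against the mean of both libraries in log2 CPM, with 1 point per feature with a mean count of at least 10 (3006 features) and dashed lines at 2-fold. The 543 points above the upper line far outnumber the 26 below the lower line, a number that was 86 with total-count scaling.

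Under the same limits, the 10 genes with the lowest ratios came largely from 2 neighbourhoods of the main chromosome. In the first, from 501938 to 507899, the sodium/solute symporter DVU0446 was 15.4-fold lower on the poised electrode (14.2 to 16.8; 601 against 6345 counts). Its neighbours were also lower: the DUF485 protein DVU0447 11.3-fold and the CBS-domain proteins DVU0444 and DVU0445 7.38-fold and 6.22-fold. DVU0446 and DVU0447 overlap at their ends on the chromosome. In the second, from 2299312 to 2302632, the RidA family gene DVU2203 was 16.9-fold lower (12.4 to 27.8; 28 against 349 counts), the tryptophan permease gene mtr (DVU2205) 11.4-fold and tryptophanase (DVU2204), which splits tryptophan into indole, pyruvate and ammonia, 8.32-fold (7.70 to 9.05). The hypothetical protein DVU2132 and its neighbour DVU2133, annotated as a sulfate exporter family transporter, were 3.96-fold and 3.05-fold lower. The last of the 10 was acs (DVU2969), the acetate to acetyl-CoA ligase, at 2.75-fold lower (2.68 to 2.82; 10403 against 19567 counts).

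**Figure D2:**
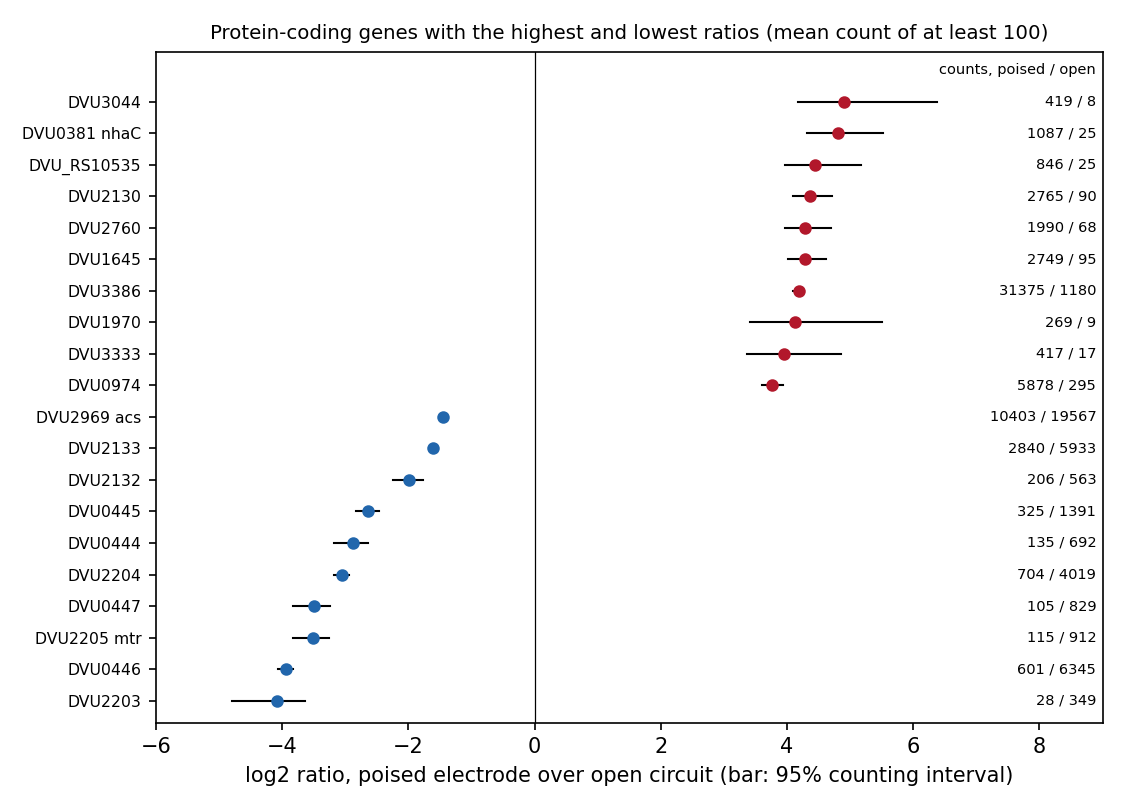
Log2 ratio, poised electrode over open circuit, of the 10 highest and 10 lowest protein-coding genes with a mean count of at least 100, with 1 library per condition, bars for the 95% counting interval and the counts of both libraries at the right. Intervals are wide where the open-circuit count is small, as for DVU3044 with 8 counts, and narrow for DVU3386 and acs.

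Genes for iron uptake and the Fur regulon, the set controlled by the ferric uptake regulator, had the highest median ratio of the lists fixed in advance. Of its 14 measured members, 10 were at least 2-fold higher on the poised electrode, none was 2-fold lower, and the median log2 ratio was 2.38. That median lay at percentile 100 of 10000 random lists matched on expression, whose medians ranged from -0.33 to 0.64 (95%). The hypothetical protein DVU3333 had the highest ratio of the list, at 15.4-fold (10.4 to 29.1). The ferrous iron transporter gene feoB (DVU2571), its member with the highest mean expression, was 1.76-fold higher (1.69 to 1.84; 7180 against 2789 counts). A protein with a TonB-dependent receptor domain, DVU0100, was the only member with a ratio below 1, at 1.41-fold lower.

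Chaperone and heat-shock genes were higher on the poised electrode as a list. Among 22 measured members 8 were at least 2-fold higher and none was 2-fold lower, with a median log2 ratio of 0.83 at percentile 99.9. The small heat-shock protein DVU2442 was 6.29-fold higher (5.98 to 6.62), and groL (DVU1976), the chaperonin GroEL and the list's most abundant member, was 1.93-fold higher with 185505 against 65864 counts. Trigger factor (tig, DVU1334) was 1.47-fold lower. The product names that formed the list also took in the heme chaperone HemW, the lipoprotein chaperone LolA and the phage-defence protein BrxL, which are not heat-shock proteins.

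Signalling genes were higher on the poised electrode as well. Of 93 measured genes for sensor kinases, response regulators and cyclic di-GMP enzymes, 33 were at least 2-fold higher and 1 was 2-fold lower, with a median log2 ratio of 0.45 at percentile 100. The chemotaxis methylesterase DVU2078, the most abundant member, was 3.36-fold higher (3.24 to 3.48), and the response regulator DVU0806 was the lower one, at 2.26-fold (2.02 to 2.54). Transposase and integrase genes had 9 of 21 measured members at least 2-fold higher and none 2-fold lower, with a median log2 ratio of 0.84 at percentile 99.3. The DDE transposase DVU0584 was 3.07-fold higher (2.66 to 3.60) and the ISDvu4 transposase DVU2004 10.8-fold higher (4.97 to 159; 55 against 2 counts), while DVU_RS05465 was 1.55-fold lower. Insertion sequences occur in near-identical copies, so the values of single transposases are uncertain. With a mean count of at least 100 required, the transposase list moved to percentile 96.2 and no longer stood apart.

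A further 5 lists stood apart on the lower side, all with ratios close to the bulk of the genes and few or no members past 2-fold. The log2 ratios of all tested features had their mode at -0.29, a median of -0.00 and quartiles of -0.35 and 0.67. A list with few or no high members can therefore have a median below 0. For ribosomal proteins 45 of 55 ratios were below 1, with a median log2 ratio of -0.35 at percentile 0.02. Only rpsO (DVU0504, 3.40-fold) and rpsP (DVU0839, 2.40-fold) were 2-fold higher, whereas rpsB (DVU0874), the most abundant, and rplW (DVU1305) were 1.54-fold and 1.83-fold lower. Aminoacyl-tRNA synthetases had 21 of 24 ratios below 1 and a median of -0.39 at percentile 0.38, in a list that also took in the tRNA methyltransferase TrmFO. Isoleucyl-tRNA synthetase (ileS, DVU1927) was 1.44-fold lower and seryl-tRNA synthetase (serS, DVU0237) 1.93-fold higher. DVU3166, annotated as an alanyl-tRNA synthetase, was 2.75-fold lower on 33 against 65 counts (1.87 to 4.52). ABC transporter genes had 78 of 111 ratios below 1 and a median of -0.26, which no matched random list reached. Their substrate-binding protein DVU0169 was 1.49-fold lower, livM (DVU0549), a branched-chain amino acid permease, 2.09-fold lower and the ATP-binding protein DVU3324 7.11-fold higher (5.88 to 8.94). In all, 7 of the ABC transporter genes were at least 2-fold higher and 1 was 2-fold lower, against 6 higher and 5 lower with total-count or upper-quartile scaling.

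**Figure D3:**
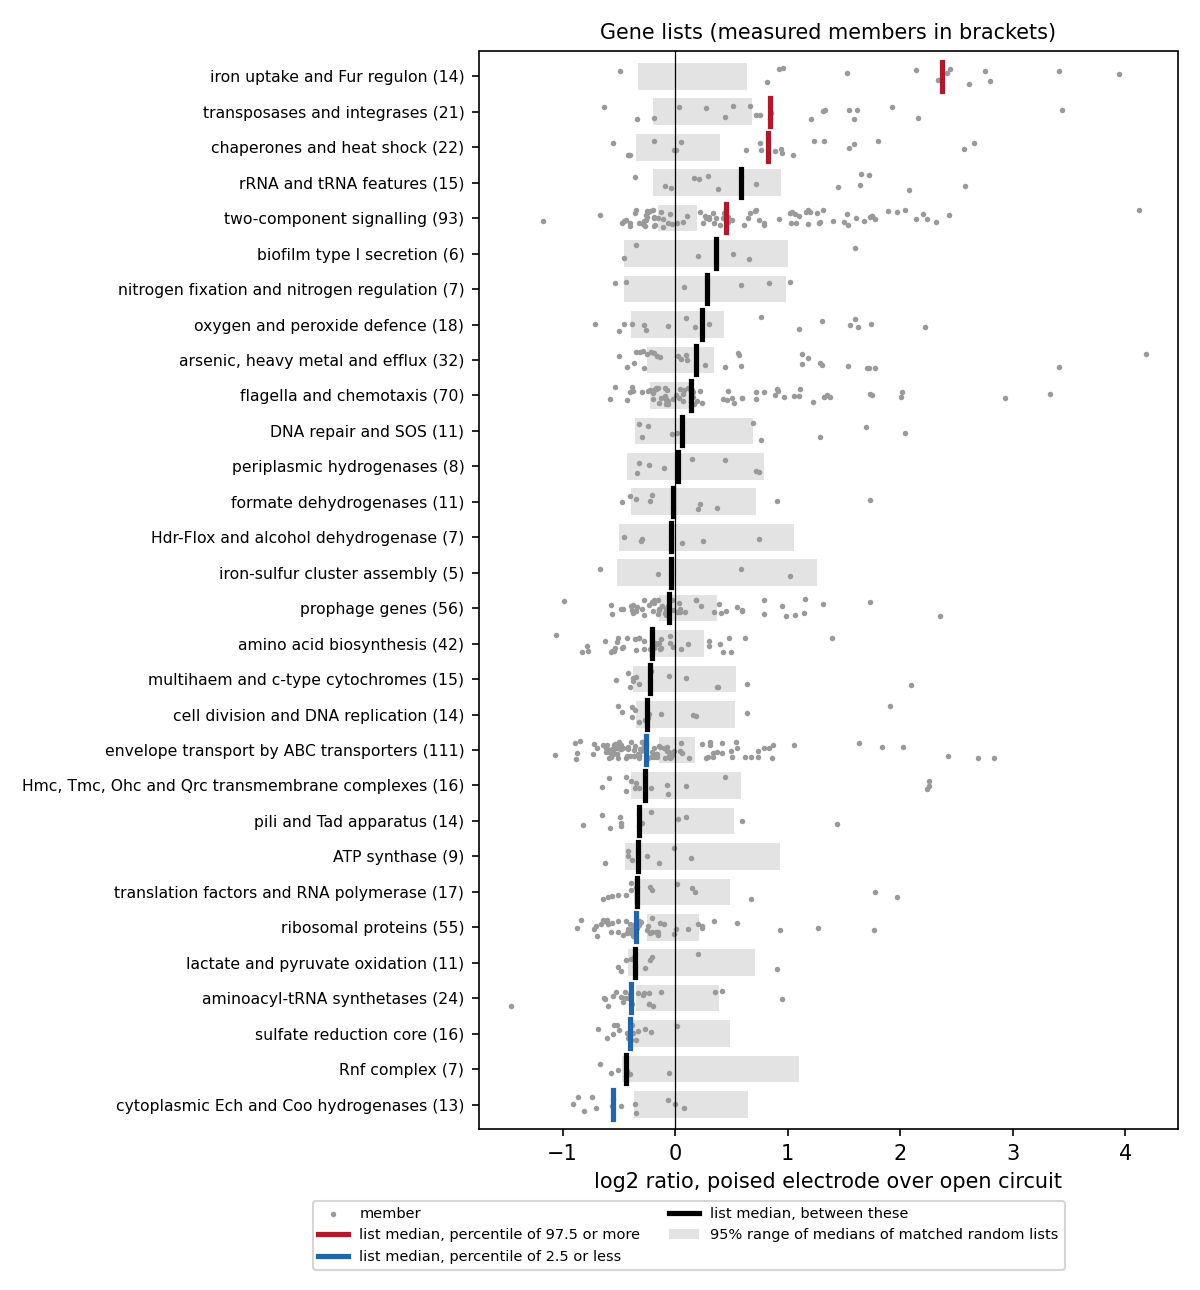
Log2 ratio, poised electrode over open circuit, of each measured member (grey points) of the 30 gene lists with at least 4 measured members, with the list median (vertical bar) over the 95% range of medians of 10000 random lists matched on mean expression (grey band), 1 library per condition. The iron uptake list, with a median of 2.38, lies farthest from its band, and the Ech and Coo hydrogenases, with a median of -0.55, have the lowest median.

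Transcripts of the sulfate reduction pathway were abundant in both libraries and slightly lower on the poised electrode. None of the 16 genes was past 2-fold in either direction, 15 had a ratio below 1, and the median log2 ratio of -0.41 lay at percentile 2.37. Adenylyl-sulfate reductase subunit alpha (aprA, DVU0847), the most abundant, was 1.29-fold lower (1.28 to 1.30; 133877 against 118564 counts), and the pyrophosphatase DVU1636 had the lowest ratio, at 1.61-fold lower (1.58 to 1.64). The sulfur carrier DsrC (DVU2776) was at 1.01-fold, with an interval from 0.989 to 1.04 that includes 1, and its log2 ratio of 0.02 became -0.24 with total-count scaling. The percentile was 2.59 with no filter on counts, 2.69 with a mean count of at least 100 and 2.73 after thinning to equal total counts, each just short of standing apart. The cytoplasmic, membrane-bound Ech and Coo hydrogenases had the lowest median of any list, -0.55, with 12 of 13 ratios below 1 and no matched random list as low. None was past 2-fold on the TMM scale, and 3 were past 2-fold lower with total-count or upper-quartile scaling. The Ech subunit DVU0432 was 1.88-fold lower (1.67 to 2.13) and 2.24-fold lower with total-count scaling, the abundant Coo protein DVU2286 1.48-fold lower, and DVU2293 lay at 1.06-fold, with a log2 ratio of 0.08 that became -0.18 with total-count scaling. Genes of 1 operon vary together, which random lists of single genes do not take into account.

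Among the enzymes that handle hydrogen and formate in the periplasm, most genes lay within 2-fold. All 8 periplasmic hydrogenase genes did, with a median log2 ratio of 0.02 (percentile 61.5) that became -0.23 with total-count scaling. The large subunit DVU1922, with 45753 and 36708 counts, was 1.17-fold lower, DVU1769 was 1.26-fold lower and the small subunit hysB (DVU1917) 1.67-fold higher (1.37 to 2.07). For formate dehydrogenases, 10 of 11 genes lay within 2-fold (median log2 ratio -0.02, percentile 55.9). The exception was the catalytic subunit gene fdnG at DVU2812, 3.33-fold higher (2.90 to 3.87; 1130 against 231 counts). The more abundant catalytic subunit gene at DVU0587, also named fdnG, was 1.39-fold lower (1.35 to 1.43). These genes share a symbol and are related in sequence, and whether reads were split between them is not known.

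The cytochromes that could carry electrons through the periplasm were mostly close to or below a ratio of 1. The type I cytochrome c3 (DVU3171), the main periplasmic electron carrier, was 1.33-fold lower (1.31 to 1.36; 23518 against 21459 counts). The first subunit of the Tmc complex (tmcA, DVU0263) was 1.25-fold lower, the cytochrome of the Rnf complex (DVU2791) 1.04-fold lower with an interval that includes 1, and the large cytochrome of the Hmc complex (hmcA, DVU0536) 1.07-fold higher, a direction that turned with total-count scaling (log2 ratio 0.10 against -0.16) and with upper-quartile scaling (-0.15). Of 15 c-type cytochrome genes found by product name, 1 was past 2-fold. That gene was DVU2524 of the cytochrome c3 family, at 4.27-fold higher (3.30 to 5.88, 364 against 57 counts), while qrcA (DVU4027) was 1.44-fold lower. The list median was -0.22, at percentile 26.0. The product names that formed the list did not take in the octaheme cytochrome DVU3144, which was also past 2-fold and is described with the Ohc complex. Within the 16 genes of the Hmc, Tmc, Ohc and Qrc membrane complexes (median -0.27, percentile 21.9), the 3 genes past 2-fold were the neighbours DVU3143, DVU3144 and DVU3145 of the Ohc complex. The octaheme cytochrome DVU3144, from 3293742 to 3295370, was 4.78-fold higher (4.48 to 5.13; 6696 against 956 counts), the iron-sulfur protein DVU3143 4.77-fold and DVU3145 4.72-fold higher. At the other end hmcE (DVU0532) was 1.57-fold lower. Both DVU3143 and DVU3145 were singled out after their values were seen.

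Several stress and surface lists had members past 2-fold without standing apart. Across all tested features 18.1% were 2-fold higher and 0.865% were 2-fold lower, and the share of higher flagella and chemotaxis genes was close to that. Oxygen and peroxide defence genes were split: 7 of 18 were at least 2-fold higher and none 2-fold lower (median 0.24, percentile 93.6), from msrB (DVU0576), a methionine sulfoxide reductase, at 4.66-fold higher to cydB (DVU3270), of the cytochrome bd oxidase, at 1.64-fold lower. Flagella and chemotaxis genes had 13 of 70 members 2-fold higher and none 2-fold lower (median 0.14, percentile 97.0). DVU2893, annotated as the flagellar rod protein FlgG, had a log2 ratio of 3.33 (41931 against 2854 counts, 9.68-fold to 10.4-fold higher), and the flagellin DVU2082 was 1.49-fold lower. Metal resistance and efflux genes had 11 of 32 members 2-fold higher and none 2-fold lower (median 0.18, percentile 89.6), from DVU3386 to DVU0061 at 1.41-fold lower. The DNA repair genes umuD (DVU2907, 4.11-fold), uvrC (DVU0801, 3.25-fold) and mutL (DVU0483, 2.44-fold) were the 3 of 11 that were 2-fold higher, with none lower (median 0.06, percentile 57.6). With total-count scaling the medians of these 4 lists were -0.02, -0.12, -0.07 and -0.20. Of 6 genes of the type I secretion system known from biofilms, the TolC protein DVU1013 was 3.02-fold higher (median 0.36, percentile 83.8), and the large protein DVU1545 was 1.37-fold lower.

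The remaining lists did not stand apart. No member was past 2-fold among 7 Rnf genes (median -0.44, percentile 4.61), 7 Hdr-Flox and alcohol dehydrogenase genes (-0.03, 72.3), 11 lactate and pyruvate oxidation genes (-0.36, 10.3) and 9 ATP synthase genes (-0.33, 18.7). Translation factors and RNA polymerase genes had a median of -0.34 (percentile 5.72), with rpoZ (DVU3242) 3.91-fold and rho (DVU1571) 3.42-fold higher of 17 genes. Amino acid biosynthesis genes had a median of -0.21 (percentile 4.56), with metE (DVU3371) 2.62-fold higher and the tryptophan synthase gene trpB (DVU0470) 2.08-fold lower of 42 genes. The pili and Tad list had a median of -0.32 (percentile 3.27), with the TadE gene DVU3342 2.71-fold higher of 14 genes. Cell division and DNA replication genes had a median of -0.25 (percentile 11.9), with the primase gene dnaG (DVU1789) 3.75-fold higher of 14. The iron-sulfur cluster gene nifU (DVU0665), 2.03-fold higher, was the member past 2-fold both of 5 cluster assembly genes (-0.04, 59.6; rnfB was matched by name) and of 7 nitrogen genes (0.28, 79.3), but was within 2-fold at 1.70-fold with total-count and 1.71-fold with upper-quartile scaling. Of 56 prophage genes, 6 were 2-fold higher and none lower (-0.06, 12.8), where 18.1% of all tested features were higher. The 15 measured rRNA and tRNA features had a median of 0.58 (percentile 83.1), with 6 that were 2-fold higher. Ferritins gave 3 measured members, too few for a percentile, with a median of -0.36.

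Total-count and upper-quartile scaling moved the median log2 ratio of the tested features by -0.25 and -0.24, and the values given here are relative to the TMM scale. With either scaling, 23 rather than 33 signalling genes and 3 rather than 6 prophage genes were 2-fold higher. The 2-fold lower genes numbered 4 for amino acid biosynthesis, 2 for ribosomal proteins (rplW among them), 1 for pili (tadA) and 1 for prophage genes (DVU2723). The iron list had 10 members past 2-fold under these scalings too. Gene length also went with the ratios: 31.4% of the 296 shortest of the tested protein-coding genes were 2-fold higher, against 13.0% of the 301 longest.

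The authors' deposited table of their own comparison lists 561 features, 530 higher and 31 lower on the poised electrode. Its smallest absolute fold is 2.00 and its largest adjusted p 0.0872 in the authors' deposited table. Of the features given there, 528 of the higher and 25 of the lower ones were also past 2-fold here, and 15 higher and 1 lower feature counted here are not in the authors' deposited table. Both comparisons rest on the same libraries, so this overlap gives no independent support.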

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

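Alternatives that remove the trend on gene length, use TMM over protein-coding genes or centre on the mode were chosen after the data were seen. The number of features at least 2-fold higher on the poised electrode stayed within 1.5 times of 543 under each alternative except the 4-fold limit, which left 175 higher and 7 lower features because it is stricter. The number of lower features, 26, was less stable: 86 with total-count scaling, 81 with upper-quartile scaling, 49 with the length trend removed, 16 with a mean count of at least 100, 15 when centred on the mode and 12 with intervals wholly past 2-fold. The scalings and the centring shift all ratios together, and the stricter filters leave fewer features. Removing the length trend also moved the median log2 ratio, by -0.095, and how far that shift accounts for the 49 lower features was not tested. Percentiles were unaffected in their call by scaling or prior count. The sulfate reduction core, at 2.37, moved to 2.59 with no filter, 2.69 with a mean count of at least 100 and 2.73 after thinning to equal total counts. Transposases and integrases moved to 96.2 with a mean count of at least 100. Other lists came to stand apart: the Rnf complex at 2.13 matched on gene length, 1.06 by list mean and 1.43 with the length trend removed; translation factors and RNA polymerase at 1.81 matched on gene length; pili and Tad at 1.29 matched on gene length and 0.07 with the length trend removed; amino acid biosynthesis at 2.25 after thinning and 0.01 by list mean; and metal resistance and efflux at 98.3 by list mean. For these lists the cause was not tested. Of 88 named genes, 63 moved past their counting interval with total-count and 62 with upper-quartile scaling. None of those past 2-fold took the other sign under any scaling or prior count. Shifts of -0.25 with total-count and -0.24 with upper-quartile scaling are too small to turn a 2-fold ratio. With either scaling nifU was no longer past 2-fold, 4 other named genes were newly past 2-fold lower (DVU0432, rplW, tadA, DVU2723), and 4 with ratios near 1 turned sign (hmcA, DVU0776, DVU2293, DVU2776). Depth limits genes with few counts, such as DVU3044 with 8 open-circuit counts. No paired analysis was possible because each condition has 1 library.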

Other observations

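The gene groups of this paragraph were chosen after the data were seen, so their percentiles describe these groups and do not test them. Regulators other than the two-component systems also had a median ratio above 1, though most lay within 2-fold. Of 113 DNA-binding transcriptional regulators 34 were at least 2-fold higher and none was 2-fold lower (median log2 ratio 0.46, percentile 100). Among 31 PilZ, HDOD, GGDEF and EAL proteins, many of which make, break or bind cyclic di-GMP, 13 were higher and none lower (median 0.75), and some of these also belong to the signalling list. Of 7 toxin-antitoxin genes 6 were higher (median 2.58). Of 481 hypothetical proteins 123 were higher and 7 lower (25.6% higher, against 18.1% of all tested features, median 0.16, percentile 99.4). No length-matched percentile was computed for the groups of this paragraph. Short genes were more often 2-fold higher, at 31.4% in the shortest against 13.0% in the longest decile. Glycosyltransferases, with 4 of 46 members higher, and porins and OmpA-like proteins, with 1 of 8, did not stand apart (percentiles 83.2 and 17.4).

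Single genes of the higher group, also chosen after their values were seen, follow. The phage shock protein gene pspA (DVU2988), which responds to damage of the inner membrane, was 3.41-fold higher on the poised electrode (65614 against 13169 counts). The lipid A synthesis gene lpxC (DVU2917) was 8.73-fold higher, the sigma factor gene rpoN (DVU1628) 7.51-fold, and the hypothetical protein DVU0772, among the 20 features with the most counts, 6.59-fold (138762 against 14412 counts). Within the chaperones htpG (DVU2643) was 3.01-fold, groES (DVU1977) 3.49-fold and dnaK (DVU0811) 2.51-fold higher. Within the iron list the P-type ATPase DVU3332 was 10.6-fold, the small iron transport protein DVU2574 5.04-fold and the flavodoxin DVU2680 4.42-fold higher. The peroxide regulator gene DVU3095 and the peroxiredoxin gene DVU2247 were 3.03-fold and 3.35-fold higher.

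The trend of the ratios with gene length was weak. Spearman's rho of log2 ratio and length was -0.14 across genes, which are not independent replicates.

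Of the tests that follow, those of a DNA background, of neighbourhoods in the iron list and of the megaplasmid were chosen after the result was seen. Removal of the length trend and TMM over protein-coding genes, both used below, were also added after the data were seen. The excess of higher over lower genes was weighed against 3 technical explanations. Under 5 other scalings the higher features made up at least 83.2% of features past 2-fold. Only total-count and upper-quartile scaling differed much from the main scale, moving the median log2 ratio by -0.25 and -0.24. These values argue against a normalization shift of that size as the whole cause. Removing the trend on gene length left 89.3% as many higher features, so length is not the whole cause either. An even floor of DNA reads would lift weakly expressed genes alone, yet 18.7% of protein-coding genes above the median expression were 2-fold higher, against 17.3% below it, although the 299 most weakly expressed genes had the largest share of any expression decile, 25.4%, so a floor stays open for these. The electrode itself, its potential, attachment and the way of collecting the cells stay open and may each contribute. They were not tested, since they differ together between 2 libraries, and whether the vessel differed is uncertain.

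The high ratios of the iron uptake and Fur regulon genes were weighed against gene length and against a single neighbourhood deciding the list. With the length trend removed the list median was 2.09, and without each of 3 neighbourhoods (DVU0303 and DVU0304, the feo genes, DVU3330 to DVU3333) it was 2.24, 2.44 and 2.14, above the 95% range of matched random lists, which reached 0.79 at most. The length trend, with decile medians from 0.36 for the shortest to -0.11 for the longest genes, is too small to explain 2.38. With 10 of 14 members past 2-fold, leaving out so few genes could not bring the median into the random range. That comparison shows only that the high ratios were not confined to a single neighbourhood. No measure of iron is among the values analysed here. The electrode itself, its potential, attachment and collection stay open, and no biological explanation was tested.

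No feature of the megaplasmid had a count in either library, although all 151 are listed in the authors' count table. Weak expression as the whole cause is argued against by the chromosome, where 0.422% of the 3077 protein-coding genes of the chromosome were without a count in both libraries (13 genes). A candidate explanation is that the plasmid was missing from the cells, or from the sequence to which the reads were aligned. These cannot be told apart from the 151 values of 0, since the reads and the alignment index were not analysed here. The nitrogen fixation genes and the catalase carried by the plasmid were for this reason not measured.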
